A study of Mus musculus with 14 samples.

How the data were processed

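RNA of hepatoblast cultures had been hybridised to Affymetrix Mouse 430A 2.0 arrays, 14 in all, with 2 cultures in each of 7 groups. On collagen these were cells with empty vector, wild-type IDH1, IDH1 R132C, wild-type IDH2 and IDH2 R172K, and on uncoated plates cells with vector and with IDH1 R132C. Replicates were separate cultures, per the series text. Doxycycline at 25 ng/mL belonged to the IDH1 experiments, per the labels' protocols, and the days each culture spent on uncoated plates were not given in the sources used here beyond the limit of 5. The species of the introduced sequences was not given in the sources used here.

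The deposited values are probe set intensity summarised by RMA (robust multi-array average), per the submitters' processing notes, which give no version or settings. RMA usually ends on the log2 scale, but the deposited intensity values were all positive and ran from 5.84 to 26770, with array medians of 134.9 to 148.3, so they were on a linear scale. Log2 of them was taken, as the plan fixed before the data were examined had set out for linear values. Detection calls were not used here. The lower quartile of the arrays lay at log2 4.72 to 4.81, and levels at or under it are close to background. The background correction could not be redone from summarised values, so that alternative was not run.

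Of 22690 probe sets, 64 were controls and 20393 carried 1 gene symbol. Another 691 carried several symbols and 1555 were absent from the platform table. These 2246 were tested as probe sets only. Each of 12393 genes was represented by its single-symbol probe set with the highest mean level over all arrays, and 4956 genes had more than 1 to choose from. The 7 group means were fitted to all 14 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with 7 residual and 5.67 prior degrees of freedom. From that fit 12 comparisons were drawn: the effect of the uncoated plate in vector and in R132C cells and the difference between these effects, R132C against vector on uncoated plates, each mutant against its wild type on collagen, their mean and their difference, and each form against vector on collagen. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called, and changes are log2 differences with their standard errors.

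Fixed lists of genes, 18 with 344 places of which 305 were measured, covered secreted proteins, metabolism and transcription factors of hepatocytes, HNF4A targets, biliary, hepatoblast, mesenchymal, blood and endothelial markers, cell cycle, hypoxia, the citric acid cycle and glutamate, cholesterol synthesis, the integrated stress response, interferon response, acute phase, YAP and TEAD targets and p53 targets. Each list was tested with camera at a preset correlation of 0.01, adjusted over the 18 lists, again with the correlation estimated from the arrays, and with fry. Statmod 1.5.0 was installed for limma's use. Members were counted past the threshold over all genes and adjusted over the list alone.

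The genes named follow a rule. Per comparison these are up to 8 of the largest rises and falls past the threshold without overlap between replicates, leaving out predicted genes. From each list, up to 4 members past the threshold with the largest change may be named, or up to 2 with the highest level where fewer than 2 pass. A set of 12 genes including Hnf4a, Cebpa, Alb, Afp, Sox9, Idh1 and Idh2 was fixed as well, to be given as values where they do not pass, and 2 of these are not reported here.

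The fit was tested on simulated data with 200 changed genes among 12393. For the plate effect in vector cells it recovered 34.3%, 85.1% and 100% of genes changed by log2 0.5, 1 and 2. For the difference between plate effects it recovered 20.9%, 68.7% and 97.0%, for R172K against wild-type IDH2 35.8%, 82.1% and 98.5%, and for both mutants together 73.1%, 100% and 100%. False calls numbered 11, 4, 5 and 12 in these 4 comparisons, and of 50 unchanged lists each, 1, 0, 1 and 0 had a camera p under 0.05. Noise was drawn independently for each simulated gene, while the correlation estimated from the arrays reached 0.93 for cholesterol synthesis. The simulated lists therefore do not test camera where members move together. Each gene's simulated noise also had the same spread in all arrays, while the R172K replicates differed most (SD 0.307 across genes, 0.181 to 0.238 in the others). The recovery and false calls for R172K and for both mutants thus do not cover groups of unequal spread.

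The alternatives tried were every probe set by itself, the mean of a gene's probe sets, genes above the 30th percentile of level only, cyclic loess, arrays centred on their median, no intensity trend, only the arrays of the groups compared, array weights, the replicate number as a block, and each array left out in turn. Where an array was left out, the lone array of its group was assumed to vary like the other groups.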

Results

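Gene expression was measured on 14 mouse arrays in hepatoblasts, the fetal liver progenitors that give rise to hepatocytes and to bile duct cells. The cells came from wild-type embryos at day 14 and were immortalised in culture, as labelled. They carried an empty vector, wild-type isocitrate dehydrogenase 1 (IDH1), the IDH1 mutant R132C, wild-type IDH2 or the IDH2 mutant R172K. IDH1 and IDH2 turn isocitrate into 2-oxoglutarate in the cytosol and in mitochondria. All 5 kinds of cell were grown on collagen, and vector and R132C cells were also kept on uncoated plates for up to 5 days, the setting the protocol names for hepatocyte differentiation. Each of the 7 groups had 2 cultures. The array medians lay between 134.9 and 148.3 intensity units, and replicate arrays correlated at r = 0.994 to 0.998 across genes. The lowest median belonged to R172K replicate 1, which also had the lowest correlation with its replicate. With 2 arrays per group, the number of arrays limits the precision of every value.

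The signal of the overexpressed genes did not separate the groups. Idh1 stood at log2 12.11 ± 0.21 in vector cells on collagen, 12.06 ± 0.10 with wild-type IDH1 and 11.89 ± 0.11 with R132C (SD, n = 2 each). Idh2 stood at log2 10.82 ± 0.017 in vector cells on collagen, 10.82 ± 0.061 with wild-type IDH2 and 10.88 ± 0.085 with R172K (SD, n = 2 each). The labels give neither the species of the introduced coding sequences nor whether they hold the 3' end these probe sets read, so the Idh1 and Idh2 signals check nothing about the labels.

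The first comparison asked which genes changed when control cells were kept on uncoated plates instead of collagen. S100g, a calcium-binding protein known from intestine and kidney, rose most, from log2 3.88 ± 0.33 to 9.80 ± 0.51 (SD, n = 2 each), a 60.5-fold change. Mptx1, a pentraxin of the intestinal mucosa, rose 56.3-fold (log2 change 5.81 with SE 0.15), the folate receptor Folr1 37.3-fold and the terminal complement component C9 34.8-fold. The sulfotransferase Sult1d1, the fatty acid hydroxylase Cyp4a12a, the protease inhibitor Serpinb1a and the lipopolysaccharide-binding protein Lbp rose 31.3-fold, 30.5-fold, 25.6-fold and 16.8-fold. Among the falls, the secreted protease Htra1 fell 15.6-fold, from log2 10.42 ± 0.16 to 6.46 ± 0.45 (SD, n = 2 each), and Fgfbp1, a carrier of fibroblast growth factors, fell 10.1-fold. The chemokine Ccl9, Adgra2, Bcl2l15, the chemokine receptor Ackr3, the branched-chain aminotransferase Bcat1 and the early response gene Fos fell 9.10-fold, 7.95-fold, 7.72-fold, 7.43-fold, 6.94-fold and 6.71-fold. In both cultures each of these 16 genes lay on the same side of both control cultures, as the rule for naming genes required. By limma with Benjamini-Hochberg adjustment, 1868 of 12393 genes rose and 1760 fell, of which 411 and 346 moved at least 2-fold. The total of 3628 came to 2293 without vector collagen replicate 1 and to 2313 without vector uncoated replicate 1. On collagen S100g, Mptx1, Folr1, C9, Sult1d1 and Cyp4a12a lay near or under the lower quartile of the arrays (log2 4.72 to 4.81), as did Adh1, Fgb, Nr1i2, Aqp1, Cebpd, Lcn2, Fas, Usp18 and Ptprc, so their folds start from a level close to background and are not exact. The same holds for the falls of Ccl9 and Adgra2, which ended near that level on uncoated plates.

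Hepatocyte genes moved in part on uncoated plates in vector cells. Of 14 measured hepatocyte transcription factors, 5 rose and none fell. Cebpa, a regulator of hepatocyte genes, rose from log2 6.23 ± 0.16 to 8.96 ± 0.16 (SD, n = 2 each), 6.63-fold, and Nr1i2, Foxa3 and Nr1h4 rose by log2 1.28 (SE 0.15), 0.96 (SE 0.28) and 0.76 (SE 0.12). Hnf4a, a central regulator of hepatocyte identity, was already at log2 11.56 ± 0.075 on collagen and its change of 0.15 (SE 0.11) did not pass (adjusted p = 0.400). The transcription factor list had an adjusted p = 0.00563 by camera, and adjusted p = 0.295 with an estimated correlation. Of 20 secreted hepatocyte proteins, 7 rose, among them transthyretin Ttr 8.33-fold, fibrinogen Fgb 8.32-fold, hemopexin Hpx 6.88-fold and Ambp 5.78-fold (adjusted p = 0.0210 by camera, and adjusted p = 0.295 with an estimated correlation). Alb, the main plasma protein of mature hepatocytes, stood at log2 4.61 ± 0.055 and 4.93 ± 0.40 (SD, n = 2 each) and did not pass (adjusted p = 0.168). Alb in all 7 groups, and Adh1 in all but vector cells on uncoated plates, lay near or under the lower quartile, so their differences elsewhere are between levels close to background. Of 21 genes named as HNF4A targets, 6 rose, including Apoc2 4.92-fold and villin Vil1 4.23-fold beside Ttr and Ambp, with a median of 0.062 and a mean of 0.52 (adjusted p = 0.0421 by camera, and adjusted p = 0.295 with an estimated correlation). The estimate for HNF4A targets was -0.0018, under the preset 0.01, so correlation among its members does not explain that loss. Directional fry, which does not set members against other genes, gave adjusted p = 0.00191 for the transcription factors, 0.000693 for the secreted proteins and 0.000230 for the HNF4A targets. Only the alcohol dehydrogenase Adh1 rose among 21 genes of hepatocyte metabolism, from log2 4.40 ± 0.16 to 6.16 ± 0.55 (SD, n = 2 each). Adjusted over the list alone, these 4 lists had the same counts of 5, 7, 6 and 1 rises and no fall.

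Markers of the 2 liver lineages went both ways. Of 16 biliary genes 4 rose and 3 fell: Sox9, Epcam and the water channel Aqp1 rose 4.07-fold, 3.55-fold and 3.25-fold, while the keratins Krt7 and Krt19 changed by log2 -0.84 (SE 0.17) and -0.28 (SE 0.081, adjusted over the list alone, 5 rose and 4 fell). Of 14 hepatoblast and fetal liver genes, 3 rose and 2 fell, the same as when adjusted over the list alone. The fetal serum protein Afp fell 2.63-fold from log2 10.64 ± 0.0080 to 9.24 ± 0.22 (SD, n = 2 each), Hmga2 changed by -0.38, and Id3 and the RNA-binding protein Igf2bp3 rose by 1.18 and 0.51 on the log2 scale. Camera found no shift of these 2 lists (adjusted p = 0.153 and adjusted p = 0.865).

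Genes of cell division fell together in vector cells on uncoated plates. All 23 measured cell cycle genes fell, by a median of log2 -1.34, among them the mitotic kinases Bub1, Aurkb and Aurka (-1.87 with SE 0.17, -1.78 with SE 0.16 and -1.58 with SE 0.17) and the thymidine kinase Tk1 (-1.54 with SE 0.22). The list had an adjusted p = 8.60e-15 by camera, and adjusted p = 0.295 with an estimated correlation. Of 16 enzymes of cholesterol synthesis, 15 fell, among them Sqle, Idi1, Cyp51 and Msmo1 by log2 values from -1.80 to -1.83, and adjusted over the list alone all 16 fell (adjusted p = 1.45e-06 by camera, and adjusted p = 0.424 with an estimated correlation). Of 19 genes of the integrated stress response, 8 fell and 2 rose, adjusted over the list alone too, with the 1-carbon enzyme Mthfd2 at -1.93 (SE 0.41) and asparagine synthetase Asns at -1.69 (SE 0.34, adjusted p = 0.0224 by camera, and adjusted p = 0.766 with an estimated correlation). Of 16 hypoxia genes, 8 fell, such as Pdk1 and hexokinase Hk2 (-0.80 and -0.71), while Ndrg1 rose 5.52-fold (adjusted over the list alone, 1 rose and 8 fell, adjusted p = 0.0224 by camera, and adjusted p = 0.694 with an estimated correlation). Of 14 YAP and TEAD targets 7 fell, adjusted over the list alone too, among them Tead1, Ankrd1 and Ajuba (-1.01, -0.94 and -0.71, adjusted p = 0.0224 by camera, and adjusted p = 0.295 with an estimated correlation). The acute-phase and inflammation list had 5 rises among 17 genes, adjusted over the list alone too, with Cebpd 5.27-fold, the chemokine Ccl2 3.55-fold and Lcn2 2.89-fold beside Lbp (adjusted p = 0.0210 by camera, and adjusted p = 0.295 with an estimated correlation).

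The other lists had no camera call in vector cells. Of 14 p53 targets 2 rose and 4 fell (adjusted over the list alone, 2 rose and 5 fell), with Fas at 1.24 (SE 0.28) and Aen at -0.95 (SE 0.14). Of 19 genes of the citric acid cycle and glutamate, 4 rose and 4 fell (adjusted over the list alone, 4 rose and 7 fell), among them Idh2 (0.51 with SE 0.077), glutamate dehydrogenase Glud1 (0.71 with SE 0.089) and Idh3a (-0.91 with SE 0.12). Of 14 interferon response genes 4 rose and 2 fell (adjusted over the list alone, 5 rose and 2 fell), with Usp18 at 0.99 (SE 0.17) and Ifit2 at -0.95 (SE 0.27). Among markers of other cell types, fibronectin Fn1 rose and the collagens Col1a1 and Col5a2 fell out of 20 mesenchymal genes (adjusted over the list alone, 1 rose and 1 fell). The pan-leukocyte marker Ptprc was the only one of 13 blood cell genes to rise, by log2 1.73 (SE 0.28), adjusted over the list alone too, and of 14 endothelial genes none passed in either count. The camera adjusted p of these lists were 0.143 for p53 targets, 0.949 for the citric acid cycle, 0.147 for interferon, 0.788 for mesenchymal, 0.788 for blood and 0.779 for endothelial genes. Median, mean and test differed in sign for 3 lists without a call: hepatocyte metabolism, hepatoblast and fetal liver, and mesenchymal genes.

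**Figure D1:**
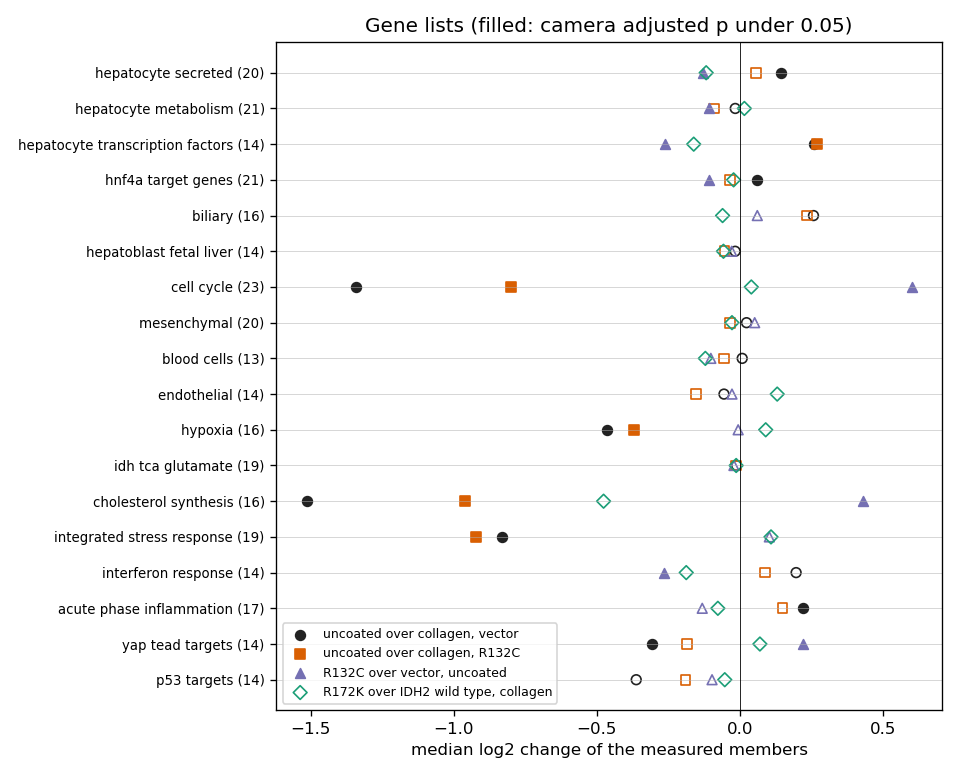
Median log2 change of the measured members of each of the 18 gene lists (number of members in parentheses) in 4 comparisons, with filled symbols where camera with its preset correlation gave an adjusted p under 0.05. The cell cycle list sits at -1.34 on uncoated plates in vector cells, -0.80 in R132C cells and 0.60 between R132C and vector cells on uncoated plates, and no filled symbol held with an estimated correlation.

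In IDH1 R132C cells the same change of surface gave a response of the same direction for most genes. Cyp4a12a rose 21.3-fold (log2 change 4.41 with SE 0.31), S100g 11.8-fold and Ambp 11.6-fold, from log2 8.34 ± 0.12 to 11.88 ± 0.32 (SD, n = 2 each). Serpinb1a, Sptssb, Pilra, ceruloplasmin Cp and Tm4sf20 rose between 6.73-fold and 10.7-fold. Htra1 fell 12.5-fold, Bcat1 7.78-fold, Bcl2l15 6.23-fold and Fgfbp1 5.61-fold, and the signalling protein Wnt7a, Adgra2, Ccl9 and Serpinb2 fell between 4.13-fold and 5.52-fold. Cebpa rose 3.87-fold and Sox9 3.94-fold, while Adh1 stayed at log2 4.31 ± 0.095 and 4.34 ± 0.20 (SD, n = 2 each, adjusted p = 0.951). Afp and Krt7 changed by -0.83 (SE 0.21) and -0.55 (SE 0.17), Hnf4a by 0.32 (SE 0.11, adjusted p = 0.0579), Alb by 0.13 (SE 0.16, adjusted p = 0.622) and Krt19 by -0.23 (SE 0.081, adjusted p = 0.0505). By limma, 1689 genes rose and 1526 fell, 287 and 205 of them at least 2-fold. Of these, 1342 rose and 1237 fell in vector cells too, where independent lists of these sizes would share 254.6 and 216.7, and no gene passed in opposite directions. These plate effects share no array but share the estimate of each gene's spread, so their lists are not independent. Across genes the plate effects correlated at r = 0.877, with genes not independent replicates. The total of 3215 came to 1820 and 2073 without R132C collagen replicate 1 or 2, and to 1660 without R132C uncoated replicate 2. Cyp4a12a, S100g, Tm4sf20, Aqp1 and Ptprc on collagen and Bcl2l15 and Bcat1 on uncoated plates lay near or under the lower quartile, so their folds are not exact.

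The lists moved in R132C cells as follows. Of 23 cell cycle genes 21 fell, among them Aurka, Aurkb and Bub1 by log2 values from -1.38 to -1.39, and all 23 when adjusted over the list alone (adjusted p = 3.57e-11 by camera, and adjusted p = 0.466 with an estimated correlation). Of the enzymes of cholesterol synthesis 6 of 16 fell, such as Idi1 and Lss (-1.25 with SE 0.38 and -1.24 with SE 0.34), and all 16 adjusted over the list alone (adjusted p = 0.000230 by camera, and adjusted p = 0.585 with an estimated correlation). Hepatocyte transcription factors had 2 rises of 14 in both counts, Cebpa and Nr1h4 (adjusted p = 0.0308 by camera, and adjusted p = 0.466 with an estimated correlation). The stress response list had 8 falls of 19, 9 adjusted over the list alone, with Mthfd2 at -1.97 (SE 0.41) and Asns at -1.66 (SE 0.34, adjusted p = 0.0234 by camera, and adjusted p = 0.660 with an estimated correlation). The hypoxia list had 6 falls and 1 rise of 16, 7 and 1 adjusted over the list alone, with Hk2 at -0.99 (SE 0.10) and Ndrg1 at 1.44 (SE 0.35, adjusted p = 0.0234 by camera, and adjusted p = 0.585 with an estimated correlation). Without a camera call, 6 of 20 secreted proteins rose and 1 fell, 6 of 21 HNF4A targets rose and 1 fell, and 6 of 16 biliary genes rose and 1 fell (6 and 1, 6 and 1, and 6 and 2 adjusted over the list alone). These included Hpx 6.16-fold, Vil1 5.14-fold and Aqp1 2.77-fold. The acute-phase list had 7 rises of 17 (7 rises and 1 fall adjusted over the list alone), with Lbp 6.52-fold and Ccl2 5.15-fold. Ptprc rose by log2 1.19 (SE 0.28) here as well, the only blood cell gene of 13 to pass. Median, mean and test differed in sign for 3 lists without a call, the HNF4A targets, mesenchymal genes and blood cell genes.

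The next comparison asked whether R132C cells responded differently to the uncoated plate. Mptx1 rose from log2 3.30 ± 0.057 to 9.11 ± 0.085 in vector cells and from 3.44 ± 0.049 to 4.04 ± 0.41 in R132C cells (SD, n = 2 each), a difference between the responses of log2 -5.21 (SE 0.22). Folr1 and C9 reached log2 9.95 ± 0.23 and 9.74 ± 0.042 in vector cells but 6.01 ± 0.45 and 6.67 ± 0.73 in R132C cells on uncoated plates (SD, n = 2 each), with differences of -3.96 (SE 0.29) and -3.10 (SE 0.35). The glucuronosyltransferase Ugt2b5 (-2.82 with SE 0.31), the secreted peptides Spink4 (-2.45 with SE 0.23) and Guca2a (-2.28 with SE 0.29), S100g (-2.36 with SE 0.35) and Naip5 (-2.25 with SE 0.36) also rose less. Adh1 rose in vector cells and not past the threshold in R132C cells, and its difference passed (-1.73 with SE 0.28, adjusted p = 0.0178). Ttr rose by log2 3.06 in vector cells and 1.15 in R132C cells, a difference of -1.91 (SE 0.21). By limma, 31 genes differed past adjusted p 0.05, all with a lower change in R132C cells and all by at least 2-fold. An unadjusted p under 0.05 was held by 694 genes, where 0.05 of the genes tested is 619.7. Cebpa (-0.78 with SE 0.29), Afp (0.56 with SE 0.30), Sox9 (-0.045 with SE 0.36), Hnf4a (0.17 with SE 0.16), Alb (-0.19 with SE 0.23), Krt7 (0.29 with SE 0.23) and Krt19 (0.042 with SE 0.11) did not pass. The count of 31 came to 20 without vector collagen replicate 2, 19 and 20 without R132C collagen replicate 1 or 2, 79 without vector uncoated replicate 2 (19 of them higher in R132C cells), 12 with dim genes left out and 55 with array weights (7 of them higher). Mptx1, Ugt2b5, Naip5 and Adh1 lay under the lower quartile in R132C cells on both plates, and all of the genes named here except Guca2a, Ttr and those that did not pass lay near or under it on collagen, so the sizes of these differences are not exact.

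**Figure D2:**
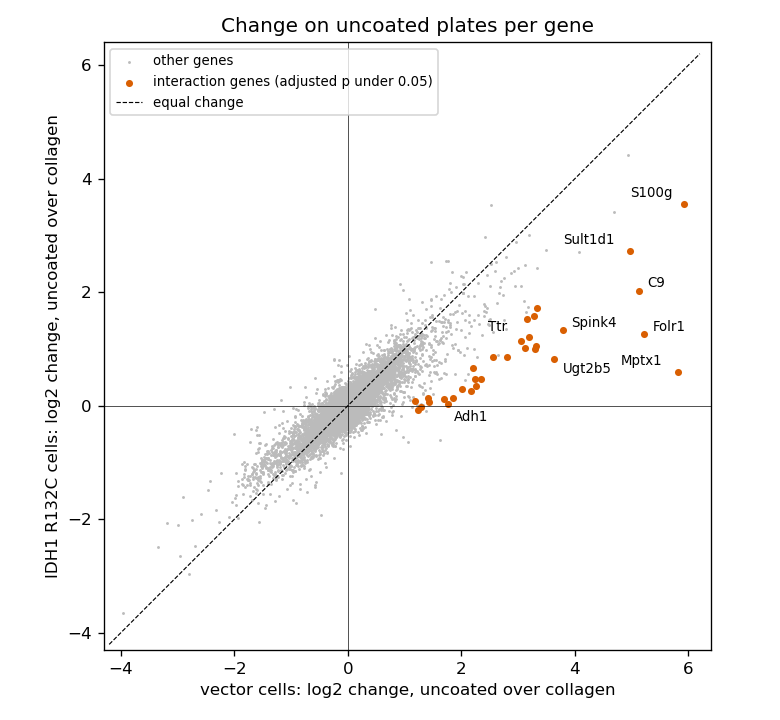
Each point is 1 of 12393 genes, with its log2 change from collagen to uncoated plates in vector cells on the x axis and in IDH1 R132C cells on the y axis, and the dashed line marks equal change. The 31 orange genes lie under the line, with Mptx1 at 5.81 in vector cells and 0.60 in R132C cells.

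Of the 18 lists, 4 had a camera call for the difference between responses. The cell cycle list fell less in R132C cells, with a median difference of 0.34 and no member past the threshold in either count, Mcm7 at 0.26 (SE 0.18) and Pcna at 0.084 (SE 0.15, adjusted p = 1.52e-07 by camera, and adjusted p = 0.443 with an estimated correlation). Cholesterol synthesis, with Hmgcs1 at 0.61 (SE 0.36) and Fdps at 0.61 (SE 0.46), had a median difference of 0.55 and none of 16 members past the threshold, adjusted over the list alone too (adjusted p = 0.00962 by camera, and adjusted p = 0.590 with an estimated correlation). YAP and TEAD targets had a median of 0.23, with none of 14 members past the threshold in either count and Ankrd1 at 0.58 (SE 0.20, adjusted p = 0.0261 by camera, and adjusted p = 0.443 with an estimated correlation). Hepatocyte metabolism had a median of -0.076, with Adh1 the only member of 21 to pass in both counts (adjusted p = 0.0488 by camera, and adjusted p = 0.443 with an estimated correlation). Outside these, Ttr passed among the secreted proteins and HNF4A targets and Id3 (-1.09 with SE 0.16) among the hepatoblast genes. Adjusted over the list alone, 2 biliary genes were higher and 1 lower, and 1 transcription factor and 1 acute-phase gene were lower. Median, mean and test differed in sign for the HNF4A targets, hepatoblast genes and stress response genes, none of which had a call.

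**Figure D3:**
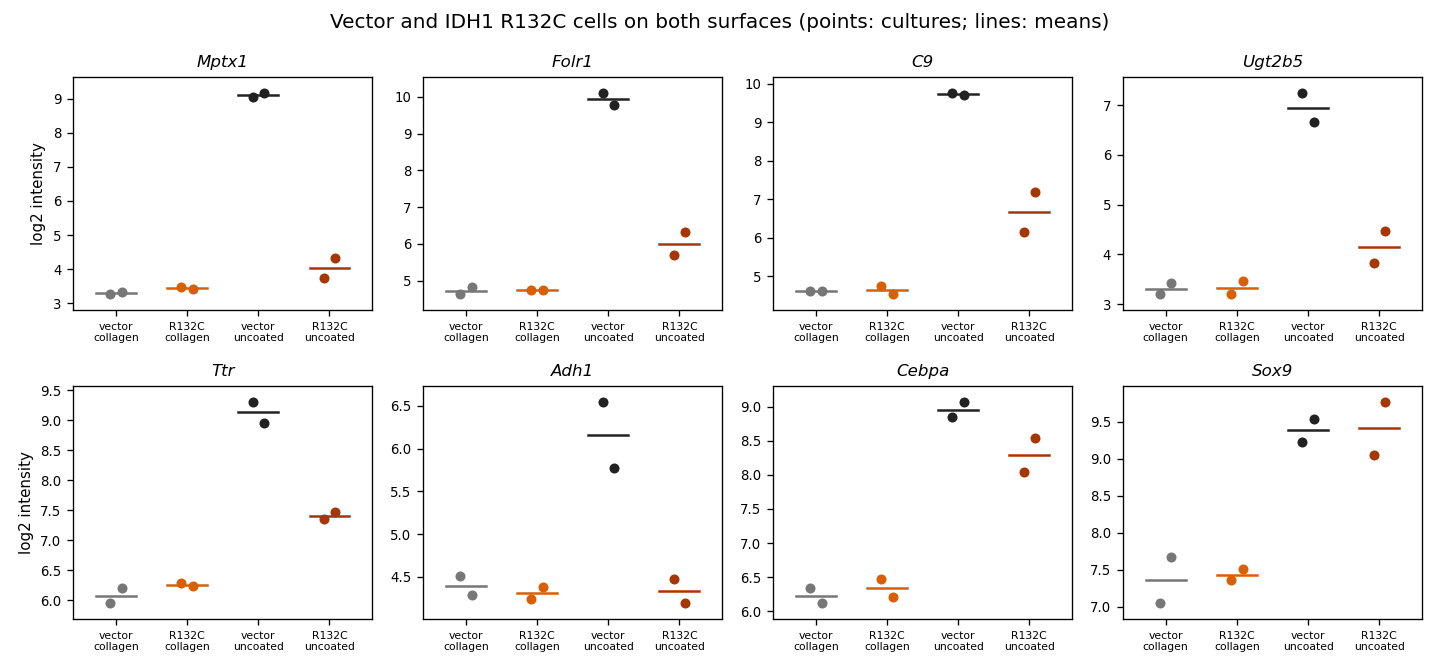
Log2 intensity of 8 genes in vector and IDH1 R132C cells on collagen and on uncoated plates, with 1 point per culture and a line at each group mean of 2 cultures. Adh1 averaged 6.16 in vector cells and 4.34 in R132C cells on uncoated plates, while Sox9 averaged 9.38 and 9.41.

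Set side by side on uncoated plates, R132C and vector cells differed in genes of both directions. Mptx1 was 33.6-fold, Folr1 15.3-fold, C9 8.39-fold and Ugt2b5 6.96-fold lower in R132C cells, where Mptx1 and Ugt2b5 lay under the lower quartile of the arrays, so that these folds are not exact. Guca2a, Spink4, the lysosomal enzyme subunit Hexa and the cytochrome Cyp4f14 were lower by 4.51-fold to 5.05-fold. The calcium-binding protein S100a4 was 3.57-fold higher, Tenm4 2.95-fold and Afp 2.72-fold, at log2 10.69 ± 0.48 against 9.24 ± 0.22 (SD, n = 2 each). Ackr3, S100a3, St8sia4, the growth factor Fgf18 and Ctla2b were higher by 2.30-fold to 2.69-fold. Ttr was 3.31-fold lower, and Adh1 was lower with R132C cells at log2 4.34 ± 0.20 (SD, n = 2), a level close to background, while Hnf4a (-0.28 with SE 0.11), Cebpa (-0.67 with SE 0.20), Alb (-0.13 with SE 0.16), Sox9 (0.030 with SE 0.25), Krt7 (0.31 with SE 0.17) and Krt19 (0.11 with SE 0.081) did not pass. By limma, 111 genes were higher and 185 lower in R132C cells, 15 and 76 of them at least 2-fold. The total of 296 came to 178 without R132C collagen replicate 1 or 2, 82 without vector uncoated replicate 1, 71 without R132C uncoated replicate 1 and 140 with only the arrays compared. No array of wild-type IDH1 on uncoated plates was used here, so this comparison does not part the mutation from overexpression or doxycycline.

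Cell cycle genes were higher in R132C than in vector cells on uncoated plates. Of 23 members 6 passed, with Mki67, Top2a, Ccna2 and Bub1 higher by log2 0.86 (SE 0.18), 0.82 (SE 0.15), 0.76 (SE 0.17) and 0.73 (SE 0.17), and 22 when adjusted over the list alone (adjusted p = 4.26e-19 by camera, and adjusted p = 0.187 with an estimated correlation). The list of interferon genes was lower, with Ifit1 and Usp18 past the threshold (-0.64 with SE 0.14 and -0.90 with SE 0.17, Ifit1 near background in both groups) and 3 of 14 adjusted over the list alone (adjusted p = 0.000853 by camera, and adjusted p = 0.100 with an estimated correlation). Hepatocyte transcription factors had 1 member lower, Nr1i2 (-1.07 with SE 0.15, near background in R132C cells), and 2 of 14 adjusted over the list alone (adjusted p = 0.00146 by camera, and adjusted p = 0.187 with an estimated correlation). HNF4A targets had Ttr and Apoc2 lower and 4 of 21 adjusted over the list alone (adjusted p = 0.00644 by camera, and adjusted p = 0.100 with an estimated correlation). Ttr was the only secreted protein of 20 and Adh1 the only metabolic gene of 21 to pass, in both counts (camera adjusted p = 0.0282 and 0.0302, adjusted p = 0.187 for both with an estimated correlation). Cholesterol synthesis had a median of 0.43 with no member past the threshold in either count (adjusted p = 0.00380 by camera, and adjusted p = 0.692 with an estimated correlation). YAP and TEAD targets had Amotl2 higher (0.51 with SE 0.11), and 7 higher and 1 lower of 14 adjusted over the list alone (adjusted p = 0.0105 by camera, and adjusted p = 0.187 with an estimated correlation). Without a camera call, the surface protein Epcam, the chloride channel Cftr (near background in both groups) and Cldn4 were lower among 16 biliary genes (2 higher and 4 lower adjusted over the list alone). Saa3 was lower among acute-phase genes, Id3 lower and Afp higher among hepatoblast genes, and Sparc higher among mesenchymal genes. Median, mean and test differed in sign for the biliary, hepatoblast, endothelial, hypoxia and stress response lists, none with a call.

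On collagen, few genes separated R132C from wild-type IDH1. Lifr, a receptor of the interleukin 6 cytokine family, was 2.48-fold higher with R132C, at log2 6.97 ± 0.42 against 5.65 ± 0.23 (SD, n = 2 each). Scel, a protein of the epithelial cornified envelope, was 2.23-fold higher and Fgf18 2.17-fold. The phosphatase Ptprr, Antxr1 and Iqgap2 were higher by log2 0.83 (SE 0.12), 0.82 (SE 0.12) and 0.82 (SE 0.13). These 6 genes were the only ones past the threshold by limma, with adjusted p from 0.0445 to 0.0471, and none was lower. An unadjusted p under 0.05 was held by 932 genes, where 0.05 of the genes tested is 619.7. Afp (0.95 with SE 0.21, adjusted p = 0.184), Hnf4a (-0.41 with SE 0.11, adjusted p = 0.300), Sox9 (0.48 with SE 0.25), Cebpa (0.39 with SE 0.20), Alb (0.17 with SE 0.16), Adh1 (-0.055 with SE 0.20), Krt7 (0.031 with SE 0.17) and Krt19 (0.047 with SE 0.081) did not pass. The cell cycle list had a median of 0.23 with no member past the threshold in either count (adjusted p = 0.000242 by camera, and adjusted p = 0.913 with an estimated correlation). The other 17 lists had no camera call and no member past the threshold over all genes. Adjusted over the list alone, 1 to 2 members passed in 6 of them: 2 acute-phase genes were higher, 2 interferon genes, 1 biliary gene and 1 transcription factor were lower, and hepatoblast genes and YAP targets had 1 each way. The count of 6 depended on which arrays were held: no gene passed without any 1 array of wild-type IDH1, R132C or wild-type IDH2 on collagen or of the uncoated groups, 2 passed without either R172K array, and 39 passed with array weights, of which 22 were lower. With dim genes left out 2 genes were lower, and with only the arrays compared 3 were lower and 1 of the 6 was called again. With the replicate number as a block 49 genes passed, 24 higher and 25 lower. No gene passed with every probe set tested by itself, the mean of a gene's probe sets, cyclic loess or centred arrays, and median, mean and test differed in sign for 6 lists without a call.

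The corresponding comparison for IDH2 set R172K against the wild-type enzyme on collagen. Complement factor Cfb was 3.65-fold lower with R172K, at log2 6.60 ± 0.032 against 8.46 ± 0.060 (SD, n = 2 each), and Ccl2 3.47-fold lower. Casd1, a sialic acid acetyltransferase, and the aromatic amino acid decarboxylase Ddc were 3.25-fold and 2.96-fold lower, and Pik3c2g and Tnnc1 2.84-fold and 2.58-fold. Among hepatocyte products, Ambp was 3.06-fold lower, Hpx 2.58-fold, and the retinol carrier Rbp4 lower by log2 -1.02 (SE 0.14). Hnf4a was lower too, at log2 10.88 ± 0.032 against 11.53 ± 0.10 (SD, n = 2 each), a 1.58-fold difference (adjusted p = 0.0162). The protease Prss23 was 3.48-fold higher, the carbonic anhydrase Car6 3.19-fold from a level near background, Wnt7a 3.01-fold, Angptl6 2.73-fold and Scel 2.72-fold, and Ampd3, Chchd10 and the coactivator Ppargc1b were higher by 2.32-fold to 2.40-fold. Afp (0.73 with SE 0.21, adjusted p = 0.105), Idh1 (-0.60 with SE 0.17, adjusted p = 0.100), Alb (-0.32 with SE 0.16), Cebpa (-0.12 with SE 0.20), Sox9 (0.013 with SE 0.25), Adh1 (0.12 with SE 0.20), Krt7 (0.011 with SE 0.17) and Krt19 (0.052 with SE 0.081) did not pass. By limma, 74 genes were higher and 141 lower, 18 and 19 of them at least 2-fold, and with centred arrays 98 were higher and 100 lower. The total of 215 came to 86 without R172K replicate 1, with 66 of the 215 among them, and to 2332 without R172K replicate 2. It also came to 36 and 14 without wild-type IDH2 replicate 1 or 2, 142 without wild-type IDH1 replicate 1, 109 without R132C collagen replicate 1 or 2, 41 with only the arrays compared and 9 with array weights, under which R132C against wild-type IDH1 had 39.

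No list had a camera call for R172K against wild-type IDH2, and adjusted p with an estimated correlation were 0.864 or higher. Secreted proteins had 3 members of 20 lower in both counts, Ambp, Hpx and Rbp4 (adjusted p = 0.172). Hnf4a was the only transcription factor of 14 to pass, in both counts (adjusted p = 0.148). Of 21 HNF4A targets Ambp and Vil1 (-1.18 with SE 0.15) were lower, and 3 adjusted over the list alone (adjusted p = 0.714). Epcam was lower among biliary genes (-0.94 with SE 0.21), Ccl2 among acute-phase genes and the monocyte marker Cd14 among blood cell genes (-0.75 with SE 0.15), and Id3 was higher among hepatoblast genes (0.58 with SE 0.12). Adjusted over the list alone, hepatoblast genes had 3 higher and 2 lower, p53 targets 2 higher and 1 lower, blood cell genes and the citric acid cycle 1 each way, interferon genes 2 lower, and biliary, acute-phase and YAP lists 1 lower each. The median of cholesterol synthesis was -0.48 with no member past the threshold in either count (adjusted p = 0.148). Median, mean and test differed in sign for the hepatoblast, mesenchymal, citric acid cycle and p53 lists.

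**Figure D4:**
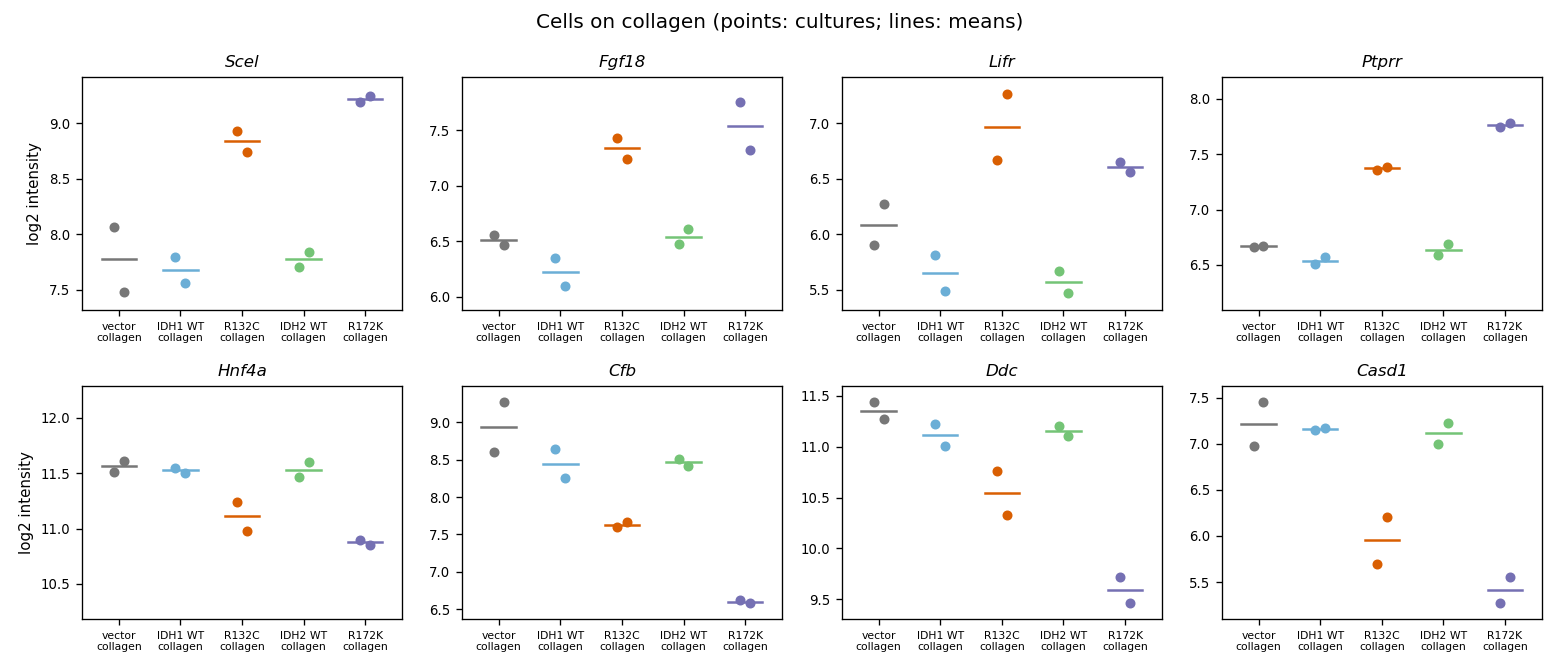
Log2 intensity of 8 genes in the 5 groups grown on collagen, with 1 point per culture and a line at each mean of 2 cultures. Hnf4a averaged 11.11 with R132C and 10.88 with R172K, and between 11.52 and 11.56 in the other groups.

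Averaged over both enzymes, the mutants differed from the wild-type forms on collagen in a set of modest changes. Prss23 was 3.18-fold higher, Wnt7a 2.49-fold, Scel 2.46-fold and Lifr 2.26-fold (n = 4 against 4), and Aqp8, Fgf18, Ampd3 and Ppargc1b were higher by 1.98-fold to 2.13-fold, Aqp8 from a level near background. Casd1 was 2.74-fold lower, Cfb 2.53-fold and Ddc 2.10-fold, and Parp14, Tnnc1, Ccl2, Adam8 and Ambp were lower by 1.92-fold to 2.09-fold. Hnf4a was lower by log2 -0.54 (SE 0.081, adjusted p = 0.00462) and Afp higher by 0.84 (SE 0.15, adjusted p = 0.0114). Alb (-0.075 with SE 0.11), Cebpa (0.13 with SE 0.14), Sox9 (0.25 with SE 0.18), Adh1 (0.034 with SE 0.14), Krt7 (0.021 with SE 0.12) and Krt19 (0.050 with SE 0.057) did not pass. By limma, 146 genes were higher and 302 lower, 8 and 5 of them at least 2-fold. The total of 448 came to 151 and 171 without wild-type IDH1 replicate 1 or 2, 115 and 112 without R132C collagen replicate 1 or 2, 109 without wild-type IDH2 replicate 2, 286 and 1803 without R172K replicate 1 or 2, and 209 with array weights, and it also dropped by more than 1.5 times without wild-type IDH2 replicate 1. Of the lists, cell cycle genes had a median of 0.12 and no member past the threshold in either count (adjusted p = 0.00948 by camera, and adjusted p = 0.958 with an estimated correlation). Ambp, Hpx and Rbp4 were lower among the secreted proteins in both counts, and Pklr, Ambp and Vil1 among the HNF4A targets in both counts. Epcam and Jag1 were lower among biliary genes (4 lower adjusted over the list alone), Tbx3 and Cdh1 lower with Afp and Id3 higher among hepatoblast genes, and pyruvate carboxylase Pcx higher among citric acid cycle genes (0.51 with SE 0.12). Median, mean and test differed in sign for 5 lists without a call, the HNF4A targets, hepatoblast, mesenchymal, stress response and acute-phase lists.

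The effects of both mutants were also set against each other. Fgf18, Lifr, Ptprr and Scel passed for R132C and for R172K, 4 genes where independent lists would share 0.0358. These comparisons share no array but share the estimate of each gene's spread. Their lists are thus not independent, and 0.0358 is only a description. No gene was shared with the mean of a gene's probe sets or with cyclic loess, and more than 4 were shared with the replicate number as a block. Of the 74 genes higher with R172K, 71 were also higher with R132C in the mean, and of the 141 lower, 134 were lower, with median R132C changes of 0.30 and -0.27 beside R172K changes of 0.68 and -0.60. Across all genes the changes correlated at r = 0.430, where genes are not independent replicates. The difference between the mutants' effects was 0.24 (SE 0.16) for Hnf4a, 1.34 (SE 0.46) for Ambp, 0.22 (SE 0.30) for Afp and 0.42 (SE 0.24) for Idh1 (R132C minus R172K). No gene passed by limma, with 653 genes at an unadjusted p under 0.05, where 0.05 of the genes tested is 619.7. Without R172K replicate 2, 85 genes passed, 2 without R172K replicate 1 and 1 without wild-type IDH1 replicate 1. Secreted hepatocyte proteins had a median difference of 0.25, with Rbp4 at 0.50 (SE 0.20) and Apob at 0.20 (SE 0.40, adjusted p = 0.0186 by camera, and adjusted p = 0.685 with an estimated correlation). The stress response list had a median difference of -0.40, with Phgdh at -0.079 (SE 0.18, adjusted p = 0.0186 by camera, and adjusted p = 0.924 with an estimated correlation), and its direction turned without wild-type IDH1 replicate 2 (adjusted p = 0.587 by camera). No list member passed in either count, and median, mean and test differed in sign for the hepatocyte metabolism, mesenchymal, interferon and p53 lists, none with a call.

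Against vector cells on collagen, R172K cells had Ambp 5.51-fold, Ccl2 5.40-fold, Cfb 5.08-fold, Tacr3 4.39-fold and Hpx 3.74-fold lower. Prss23, Wnt7a, Car6 and Htra1 were 3.47-fold, 3.31-fold, 3.30-fold and 2.75-fold higher, with Car6 in vector cells and Tacr3 in R172K cells near background, and Hnf4a was lower by log2 -0.68 (SE 0.11, adjusted p = 0.00706). By limma, 142 genes were higher and 387 lower. That total of 529 came to 70 without vector collagen replicate 2, 331 without R132C collagen replicate 1 or 2, 216 and 2596 without R172K replicate 1 or 2, 45 with only the arrays compared and 40 with array weights. R172K cells had the hepatocyte transcription factors lower, with Hnf4a among 2 members of 14 past the threshold and 3 adjusted over the list alone (adjusted p = 0.0295 by camera, and adjusted p = 0.614 with an estimated correlation). Hypoxia genes had a median of 0.15 and no member past the threshold (adjusted p = 0.0295 by camera, and adjusted p = 0.666 with an estimated correlation). Wild-type IDH1, wild-type IDH2 and R132C each gave 0 genes against vector on collagen by limma. They had 128, 116 and 936 genes at an unadjusted p under 0.05, where 0.05 of the genes tested is 619.7. The wild types lay far under 619.7, so a count near 619.7 in this fit does not show that no gene changed. Hnf4a differed from vector by -0.036 (SE 0.11) with wild-type IDH1, -0.028 (SE 0.11) with wild-type IDH2 and -0.45 (SE 0.11) with R132C, none past the threshold. R132C had 14 genes without vector collagen replicate 1 and 10 with array weights. R132C cells had higher cell cycle genes (median 0.24, adjusted p = 1.91e-06 by camera, and adjusted p = 0.888 with an estimated correlation) and lower interferon genes (median -0.13, adjusted p = 0.0437 by camera, and adjusted p = 0.531 with an estimated correlation) by camera, with no member past the threshold over all genes. With wild-type IDH1, stress response genes had a median of 0.22 (adjusted p = 0.00749 by camera, and adjusted p = 0.829 with an estimated correlation) and secreted proteins one of -0.10 (adjusted p = 0.0392 by camera, and adjusted p = 0.521 with an estimated correlation). With wild-type IDH2, HNF4A targets had a median of -0.071 (adjusted p = 0.0495 by camera, and adjusted p = 0.243 with an estimated correlation).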

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

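Of the tests in this part, the one of RNA degradation and the count of splits balanced for replicate number were chosen only after the result was seen. Groups of 2 were not tested for a stray array. R172K replicate 1 stood apart from the other 13 arrays, with a mean intensity of 879.5 (939.9 to 955.1 in the others), a median of 134.9 (144.8 to 148.3) and a second principal component of -27.1 (-5.64 to 10.7). The R172K pair had the lowest weight (0.331 each, 1.02 to 1.44 in the other groups), and its replicates differed most (SD 0.307 across genes, 0.181 to 0.238 in the others).

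The response to the uncoated plate differed between R132C and vector cells in a test of the difference itself for 31 genes, all with the lower change in R132C cells, while 19 of 79 were higher without vector uncoated replicate 2 and 7 of 55 with array weights. By the same kind of test, camera with its preset correlation, 4 lists differed, with mean differences of 0.35 for cell cycle genes, 0.45 for cholesterol synthesis, 0.17 for YAP and TEAD targets and -0.19 for hepatocyte metabolism. On collagen, the effects of R132C and R172K differed in secreted hepatocyte proteins (mean 0.34) and in the integrated stress response (mean -0.40). None of these 6 list differences held with an estimated correlation, and that of the stress response turned its direction without wild-type IDH1 replicate 2 (adjusted p = 0.587). Outside the gene-level comparisons, 422 of 2246 probe sets without a single gene name passed for the uncoated plate in vector cells (250 of them lower, 18.8% beside 26.6% of named probe sets), and 3 passed for the difference between plate effects.

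The smaller response of R132C cells was weighed against 1 common scaling of the whole log2 response, as a slower response or fewer days in culture might give. Fewer responding cells would dilute the intensities and not scale log2 changes by 1 factor, so this test does not cover them. With the vector changes multiplied by a common factor of 0.787, 17 of the 31 genes stayed lower. The factor itself was 0.619 and 0.955 when taken from single replicates, which left 3 and 30 genes, so a common scaling and a change of particular genes cannot be told apart with 2 arrays per group. RNA degradation was argued against, since 2 of 2 R132C arrays on uncoated plates lay inside the range of the other 12 for the 3' to 5' ratios of Gapdh and beta-actin. An effect of the mutation stays open and untested here, since wild-type IDH1 was not measured on uncoated plates.

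Genes of the intestine were among the largest rises in vector cells on uncoated plates, such as S100g, Mptx1, Guca2a and Spink4. Intestinal epithelial cells in the culture were weighed with a separate list of intestinal transcripts, of which 8 of 15 rose, with a median of 0.40. That median was under the rise of 1 set for such cells, but more than the share set against them rose, so they cannot be told apart from a change within the hepatoblasts. Among genes picked from that list after their values were seen, Cdx2 was already at 9.59 on collagen in vector cells and reached 11.32, and Lgals4 went from 11.98 to 13.76, while Lct, Slc5a1, Mep1b and Lyz1 stayed near the floor.

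More genes were called for R172K (215) than for R132C (6) on collagen. This order turned round with array weights, which gave 9 for R172K and 39 for R132C, and without wild-type IDH2 replicate 2 R172K had 14. Without R172K replicate 1, 86 genes were called for R172K, over the 50 set before, and 2 for R132C. That fit assumes the lone array varies like the other groups, while the R172K replicates differed most of all pairs. The count of 86 therefore cannot decide whether replicate 1 alone was the whole source. All 215 genes kept the sign of their change without R172K replicate 1. Replicate 2 had helped to pick these genes, so the kept signs are no separate support. An overall intensity shift of that array was argued against, since 198 genes were called with each array centred on its median. A difference between the enzymes stays open and the direct test of R132C against R172K effects called 0 genes.

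For both mutants against both wild types, 1 of 35 splits of the 8 arrays called as many genes, the real one, with 333 genes when only these arrays were fitted. The highest other split called 18, the one by replicate number. Most other splits part the 2 cultures of a group, so the 8 arrays cannot be taken as exchangeable. The other splits that keep each group whole called 0 genes each, and they are too few to exclude chance for the count of 333. Same-numbered arrays on collagen deviated together, and of the 18 splits with 2 arrays of each number on either side the real one was 1, too few for a share under 0.05.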

How the results depend on the processing

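All tests in this part were planned. Among the named genes no call changed direction, while 1 gene that was not called and 1 list that was called did. Of 131 other probe sets of called named genes, 7 had the opposite sign, none past the threshold. Csf1r for the uncoated plate in vector cells came to 0.49 with the mean of a gene's probe sets, against -0.036 from its brightest probe set. The stress response list for R132C minus R172K turned its direction without wild-type IDH1 replicate 2 (adjusted p = 0.587), and over the arrays left out its adjusted p ran from 2.16e-11 to 0.917. The cause was not tested for these or for the values that follow, except where fewer arrays or genes were tested.

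With every probe set by itself, 5848 and 5244 probe sets passed for the plate effects in vector and R132C cells, and 0 for R132C against wild-type IDH1. For that last comparison 0 genes passed with the mean of a gene's probe sets, cyclic loess or centred arrays, and the overlap of R132C and R172K calls was 0 with the mean of probe sets and with cyclic loess. With dim genes left out the difference between plate effects had 12 genes. With array weights the counts were 55 for that difference, 39 for R132C against wild-type IDH1, 9 for R172K against wild-type IDH2, 209 for both mutants, 10 for R132C against vector on collagen and 40 for R172K against vector. With only the arrays compared, 140 genes passed for R132C against vector on uncoated plates, 41 for R172K against wild-type IDH2 and 45 for R172K against vector. Scaling moved the split of higher and lower genes: for R172K against wild-type IDH2 it was 74 and 141, 97 and 103 with cyclic loess, and 98 and 100 with centred arrays. For both mutants it was 146 and 302, 189 and 233, and 185 and 243, and for R172K against vector 142 and 387, 198 and 279, and 199 and 281.

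Leaving out 1 array at a time gave 2293 to 4251 genes for the plate effect in vector cells, 1660 to 3916 in R132C cells, 19 to 79 for their difference and 71 to 386 for R132C against vector on uncoated plates. On collagen it gave 0 to 9 for R132C, 14 to 2332 for R172K, 109 to 1803 for both, 0 to 85 for R132C minus R172K, 0 to 14 for R132C against vector and 70 to 2596 for R172K against vector. Wild-type IDH1 and IDH2 against vector stayed at 0.

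The labels do not say that a replicate number marks a shared day or batch. Same-numbered arrays deviated together in all 10 pairs of groups on collagen (r = 0.11 to 0.49) and in the pair on uncoated plates (0.26). Across plates 2 of 10 pairs lay over 0.1 (-0.041 to 0.22), so the arrays as a whole were not taken as paired. For comparisons within collagen the main fit thus leaves out a shared deviation that these arrays do show. As a hint from the data, a replicate block gave 54 genes for the difference between plate effects, 505 for R132C against vector on uncoated plates, 49 (24 higher and 25 lower) for R132C and 480 for R172K against wild type, 792 for both, 33 and 904 for R132C and R172K against vector on collagen, and 34 shared calls of R132C and R172K.

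Of 249 calls of named genes, 30 were lost with array weights, 37 with only the arrays compared, 27 with the mean of probe sets, 13 with cyclic loess and 12 with centred arrays, and 314 of 1176 when an array was left out. In the first 8 comparisons all 30 camera calls were lost with an estimated correlation (adjusted p from 0.100 to 0.958), 17 with the directional test of fry, 10 with its mixed test, 4 with cyclic loess, 3 with dim genes left out and 1 with the replicate block, and when an array was left out 109 list calls were kept, 38 were lost and 1 turned round. For HNF4A targets the estimated correlation was -0.0018, under the preset, so a loss with the estimate need not mean that members move together. Signal over background limits genes under the lower quartile, and the background correction was not run.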

Other observations

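The tests of cross-condition lists in this part were chosen before their results were seen, and the symbol families and the intestinal genes named here were noticed only after their values were seen. Of 158 families of genes that share the start of their symbol, the nucleoporins (Nup) fell on uncoated plates in vector and R132C cells, with 13 and 12 of 16 past the threshold (camera adjusted p = 1.28e-05 and 1.53e-05, adjusted p = 0.783 and 0.873 with an estimated correlation). Nup210 changed by log2 -1.23 and -1.13 and Nup107 by -1.05 and -0.98. Genes starting with Atp, among them the proton pump subunits Atp6v0d1 and Atp6v1e1, had 20 rises and 3 falls of 65 in both kinds of cell (camera adjusted p = 0.0317 and 0.0419, adjusted p = 0.783 and 0.873 with an estimated correlation). Between R132C and vector cells on uncoated plates, 7 of 63 cytochromes (Cyp) were lower, such as Cyp4f14, Cyp2c65 and Cyp1a1 at -2.17, -1.92 and -1.59 (camera adjusted p = 0.0289, adjusted p = 0.982 with an estimated correlation).

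Of 11 intestinal genes noticed among the largest changes, 11 rose on uncoated plates in vector cells, 6 rose in R132C cells, and 10 differed between these responses. Picked for their changes, these 11 do not stand for intestinal genes in general. In the separate list of 15 intestinal transcripts, 8 rose in vector cells, 1 rose in R132C cells and 0 differed between the responses. Muc13, a membrane mucin and 1 of the 11 noticed genes, went from log2 5.54 to 7.80 in vector cells. The mean level of the risers minus that of the fallers of the vector plate effect was 0.89 and 0.52 in the vector arrays on uncoated plates, -0.62 and -0.15 in the R132C arrays there, and -2.86 to -2.18 on collagen, with R172K at -2.67 and -2.86.

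One hypothesis was that mutant IDH shifts the same genes in both enzymes and settings. The 185 genes lower in R132C than vector cells on uncoated plates had a median change of -0.17 for R172K against wild-type IDH2 on collagen, outside the range of -0.077 to -0.0068 of 95% of 10000 random lists of like level, and 139 were lower. The 111 genes higher there had a median of 0.13 for R172K, and 84 were higher. Leaving out each array gave medians of -0.22 to -0.12 and of 0.063 to 0.18. These comparisons share no array, so the values leave partly shared changes possible, though R172K counts fell to 9 genes with array weights. The random lists draw genes singly, while genes of a list may move together. All 411 genes that rose at least 2-fold in vector cells on uncoated plates also had a median of -0.17 for R172K. The 185 genes were therefore not told apart from plate risers as a whole.

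A second hypothesis was that mutant cells on collagen lie further from the state reached on uncoated plates. The 411 genes that rose at least 2-fold in vector cells had a median of -0.17 for R172K against wild-type IDH2, with 284 lower and -0.22 to -0.12 when arrays were left out. For R132C against wild-type IDH1 their median was 0.022, inside the range of random lists (percentile 86.6). The fallers were not tested, and their mean level did not separate R172K (9.38 and 9.57) from wild-type IDH2 (9.49 and 9.44). The score of R172K replicate 1 was -2.67, as in wild-type IDH2 replicate 1, while replicate 2 had -2.86 with R172K and -2.49 with wild-type IDH2. Across all genes the vector plate effect correlated at r = -0.189 with the R172K change and at -0.057 with the R132C change. The risers were lower with R172K than with wild-type IDH2 in both replicates (6.70 against 6.82 and 6.71 against 6.95). In replicate 1 the fallers (9.38 against 9.49) and the array median (log2 7.08 against 7.18) were lower too. Lower risers apart from the level of the whole array were thus seen in replicate 2 only. A shift of the whole state was not shown.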
